A study of Danio rerio with 24 samples.

How the data were processed

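RNA from brain samples of adult male zebrafish was measured on 24 single-colour Agilent arrays, 6 for each of 4 atrazine doses: 0, 0.3, 3 and 30 ppb. The labels put the exposure at 1 to 72 hours after fertilization and the age at 5 to 6 months, with 3 weeks of breeding and 20 to 30 fish per tank. Sample labels and the series title name brain, whereas the series design text names gonadal tissue; the sample labels were followed. The labels do not say which tank, clutch or fish a sample came from.

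The authors scanned the arrays with Agilent Feature Extraction 11.5.1.1, and per the file headers the deposited scanner files hold raw and background-subtracted signal intensity for 180880 spots per array, of which 176026 are not controls. The authors' series matrix holds log2 values. Its 24 columns correlated at 1 with the log2 processed signal of their own array, and their medians lay between -3.18 and -2.27. The authors' 3 probe lists, 1 per dose, give a p-value and a log2 difference for each listed probe, and their list of genes altered at all doses gives a direction in words.

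Spots marked as outliers by the scanner software were set to missing, spots of 1 probe were averaged, and each array's 75th percentile was subtracted from the log2 processed signal. A probe entered when it was well above background on at least 6 of the 24 arrays. Of 128291 probes, 31.1% could be paired with a gene through a RefSeq accession; 13547 genes were paired. Other probes were kept under their accession or probe name, each name as 1 target, which gave 89045 targets on the array, 72590 tested targets and 12308 tested genes with a symbol. The probes of 1 target were averaged. Positions in a genome were not used, since no reference genome was supplied.

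Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with data.table (version 1.17.8) for reading the files. All 4 groups entered 1 fit, and 2-sided p-values were adjusted over the 72590 targets by the Benjamini-Hochberg method, with a threshold of 0.05. The comparisons were each dose against control, all exposed arrays against control, a trend over dose ranks with weights -3, -1, 1 and 3, any difference among the 4 groups, and each pair of doses. Fold changes are log2 with the moderated standard error (SE). Replicates were arrays, 6 per group, and their number limits the precision. The arrays filled 6 slides of 4, each slide with 1 array of every dose in the same position order, and were scanned on 3 days. Slide, scan day and replicate number were added as blocks in alternatives.

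Gene lists were written before the data were examined: 41 lists of neurotransmitter, neuroendocrine, immune, metabolic and housekeeping genes and of markers of brain and other cell types, of which 40 had at least 5 tested members. The list of mitochondrial genome genes had no member on the array. Lists were tested with camera at a preset correlation of 0.01 on the 50342 targets measured on all 24 arrays, adjusted over all lists and the 3 doses (over the lists alone for all exposed arrays, and over lists and pairs of doses for the comparisons between doses). The tests were repeated with a correlation estimated from the data and with fry, which tests whether a list's genes move on balance in 1 direction without comparing them with other genes. The level of a list on an array is the median deviation of its members from their mean over all arrays.

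Genes were named by a rule fixed in advance. For each dose it takes the 10 genes with a symbol with the largest rise and the 10 with the largest fall among those past the threshold, or the 5 with the smallest unadjusted p where fewer than 5 pass. It takes 10 genes for each overall test, up to 4 members of each called list, and 20 neuroendocrine genes whatever their values. Genes named outside the rule are marked as chosen after their values were seen.

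The fit was tested on simulated data, with 50 genes set to each fold among 50342 simulated genes. It recovered 16% at 2-fold, 54% at 4-fold, 84% at 8-fold and 98% at 16-fold. There were 9 false calls, 0 calls at the other doses, and 1 shifted list called with 0 others. Noise was drawn independently for each gene, so differences shared by many genes of an array were absent. These counts therefore do not show the error rate on the real arrays. Alternatives covered background correction (normexp, offset 50), scaling, probe filters, probe summaries, variance priors, array weights, blocks, the authors' values, other tests, leaving out each array, splitting the controls and other splits of the samples (100 drawn). Exchanges of labels within slides were added after the data were seen. No sample was left out of the reported fit.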

Results

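Gene expression was measured in the brains of adult male zebrafish exposed as embryos to 0, 0.3, 3 or 30 ppb of atrazine, a triazine herbicide, with 6 arrays per dose. The series title poses the question of lasting neuroendocrine effects of the early exposure. The share of spots well above background had a median of 76.8% over the 24 arrays and ranged from 35.8% to 91.2%. It lay below 50% on control replicate 3 (35.8%), 3 ppb replicate 6 (37.3%) and 30 ppb replicate 4 (41.6%). Markers of other tissues differed among arrays: the level of the liver list was 1.5 ± 2.48 log2 (SD, n = 6) in controls, with 6.22 on control replicate 4, against -0.91 ± 0.33 at 0.3 ppb, -0.38 ± 0.83 at 3 ppb and -0.23 ± 1.57 at 30 ppb. The median log2 change of all targets against control was -0.03 at 0.3 ppb, 0.22 at 3 ppb and 0.07 at 30 ppb. Scaling to the array median moved it by -0.14 at 3 ppb, and by less than 0.1 at the other doses.

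Among the genes that fell at 3 ppb were chemokine, immunoproteasome and interferon-inducible genes. The chemokine ccl34b.4 was 85.8-fold lower than in controls (log2 change -6.42 ± 0.59, SE, n = 6 per group, adjusted p = 2.35e-05), below the control mean in 6 of 6 arrays. The chemokine ccl38a.4 was 40.8-fold lower (-5.35 ± 0.69, adjusted p = 0.0031, 6 of 6), and ccl38a.5 and ccl38.1 fell by 3.90 and 3.39 on the log2 scale. The immunoproteasome subunits psmb13a, psmb8a and psmb9a, which cut peptides for display to T cells, fell by 3.25, 3.18 and 2.68 (adjusted p from 0.0139 to 0.0428). The interferon-inducible genes gig2i, gig2h and gig2g fell by 4.39, 3.16 and 3.12, and lpar5a, a receptor for lysophosphatidic acid, by 3.04. At 3 ppb gig2h was well above background on 3 of 6 arrays and gig2i, gig2g and psmb8a on 4 of 6, so the sizes of their falls rest partly on signal near background. Over all targets 6 of 34 genes of the interferon-response list fell, and the list was not called with an estimated correlation (adjusted p = 0.237 with an estimated correlation).

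A few genes of leukocytes and antigen display fell with them at 3 ppb, 3 of 32 in the leukocyte list (adjusted p = 0.237 with an estimated correlation). The microglial complement gene c1qa changed by -2.39 ± 0.42 (SE, n = 6 per group, adjusted p = 0.0227), the leukocyte cytoskeleton genes rac2 and coro1a by -2.53 ± 0.51 (0.0463) and -1.98 ± 0.41 (0.0492), and the class I antigen genes b2m and mhc1zba by -2.00 ± 0.34 (0.0227) and -1.57 ± 0.30 (0.0399). The chemokine ccl39.1 fell by 2.67, the protease adam8a by 2.98 and the oxysterol receptor gpr183a by 2.60. Pineal aanat2, which makes the precursor of melatonin, fell by 1.72 (adjusted p = 0.0341, lower in 6 of 6). The genes with a symbol that rose were osgepl1, a tRNA modification gene (0.96 ± 0.20, adjusted p = 0.0463), and wdr48b, a cofactor of deubiquitinating enzymes (0.94 ± 0.19, adjusted p = 0.0492). The next 3 by p, gcgb (1.47), mapk8a (1.2) and tsfm (0.96), had adjusted p from 0.0502 to 0.06. The level of the leukocyte list was 0.94 ± 0.85 log2 (SD, n = 6) in controls and -0.73 ± 0.64 at 3 ppb, while the liver list was also lower at 3 ppb.

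In all, 111 targets passed at 3 ppb, 28 higher and 83 lower; 2 of the higher and 30 of the lower had a gene symbol, and 14864 targets had an unadjusted p under 0.05. The count was 17 with slide as a block and 90 with scan day as a block, and 3 of 32 exchanges of labels within slides, the real one included, gave as many. Within scan day 1 (3 arrays per group) limma called 0 targets with 4525 at unadjusted p under 0.05, and within scan day 2 (2 per group) 0 with 7529; scan day 3 held 1 array per group and gave no value. Without the 3 arrays with weak signal 3 targets passed. Leaving out single arrays, the count lay between 4 (without 3 ppb replicate 2) and 4108 (without control replicate 1). The change of ccl34b.4 stayed between -7.80 and -5.19 over 46 alternatives and passed in 42. Over their alternatives the genes named here kept their direction at 3 ppb, but aanat2 passed in 27 of 46, rac2 and coro1a each in 15 of 47, psmb8a and osgepl1 each in 14 of 46, and wdr48b in 11 of 47.

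**Figure D1:**
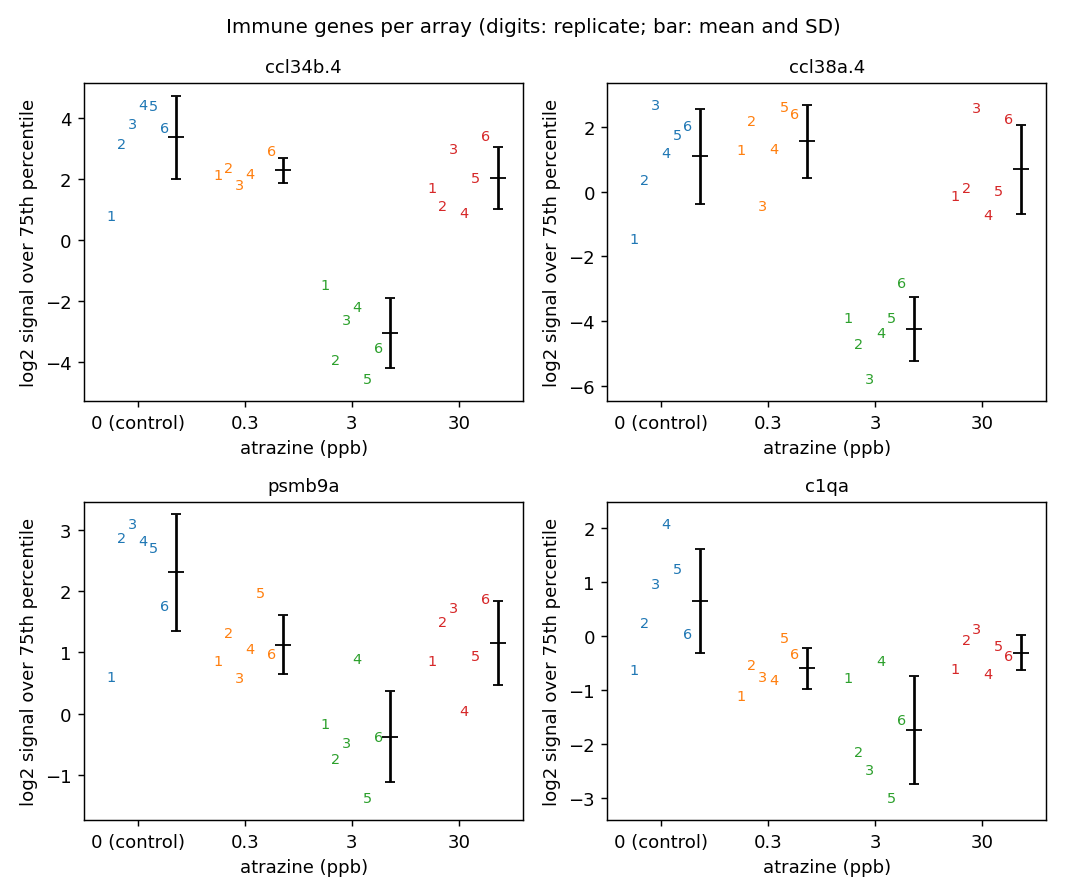
Log2 signal over each array's 75th percentile for ccl34b.4, ccl38a.4, psmb9a and c1qa by atrazine dose; digits are replicate numbers and bars are means with SD (n = 6 arrays per dose, 5 for ccl34b.4 at 0.3 ppb). All 6 arrays at 3 ppb lie below all other arrays for ccl34b.4 and ccl38a.4.

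At 0.3 ppb no single gene passed the threshold. The genes nearest to it in the upward direction included the synaptic organizer cbln2a (log2 change 2.66 ± 0.56, SE, n = 6 per group, adjusted p = 0.192), dennd4a (2.84 ± 0.63) and the photoreceptor genes arr3a (3.90 ± 0.89) and pde6gb, all at adjusted p = 0.192. In the downward direction they included the leukocyte protease gene adam8a (-3.03 ± 0.58) and the pancreatic enzyme gene cpa5 (-3.84 ± 0.76). limma called 0 targets, with 13079 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0725; a per-gene test without moderation called 1 after adjustment. The count was 0 with slide or scan day as a block, 0 within scan day 1 (4187 at unadjusted p under 0.05) and 0 within scan day 2 (7300). It was 814 without control replicate 1.

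At 30 ppb the clock gene nr1d1, which encodes a repressor of the circadian feedback loop, fell. It was 4.00-fold lower than in controls (log2 change -2.00 ± 0.25, SE, n = 6 per group, adjusted p = 0.00355), lower in 6 of 6 arrays, against -0.16 ± 0.25 at 0.3 ppb and -1.07 ± 0.25 at 3 ppb, where it did not pass (adjusted p = 0.761 and 0.0675). Over dose ranks it fell by 0.69 per step of dose rank (adjusted p = 6.62e-04). The other 2 targets that fell at 30 ppb, and the other 2 that fell with dose rank, have no gene name. Of the remaining named genes, ccl39.1 lay nearest to the threshold at 30 ppb, with a log2 change of -2.88 ± 0.47 (adjusted p = 0.0573); adam8a followed with -3.36 ± 0.58 (adjusted p = 0.0774), and cpa5 had -4.28 ± 0.76 (adjusted p = 0.0828). At 30 ppb 3 targets passed, with 11471 at an unadjusted p under 0.05, and 3 passed for the trend, with 11014. With slide as a block both counts were 3, and with scan day as a block both were 4. Within scan day 1 and within scan day 2, limma called 0 for both; 4423 and 8134 targets had an unadjusted p under 0.05 at 30 ppb, and 3643 and 7227 for the trend. Without control replicate 1 the counts were 1052 and 329, and without 3 ppb replicate 1 both were 5. At 30 ppb the count was 6 without control replicate 2 and 5 without 3 ppb replicate 5.

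**Figure D2:**
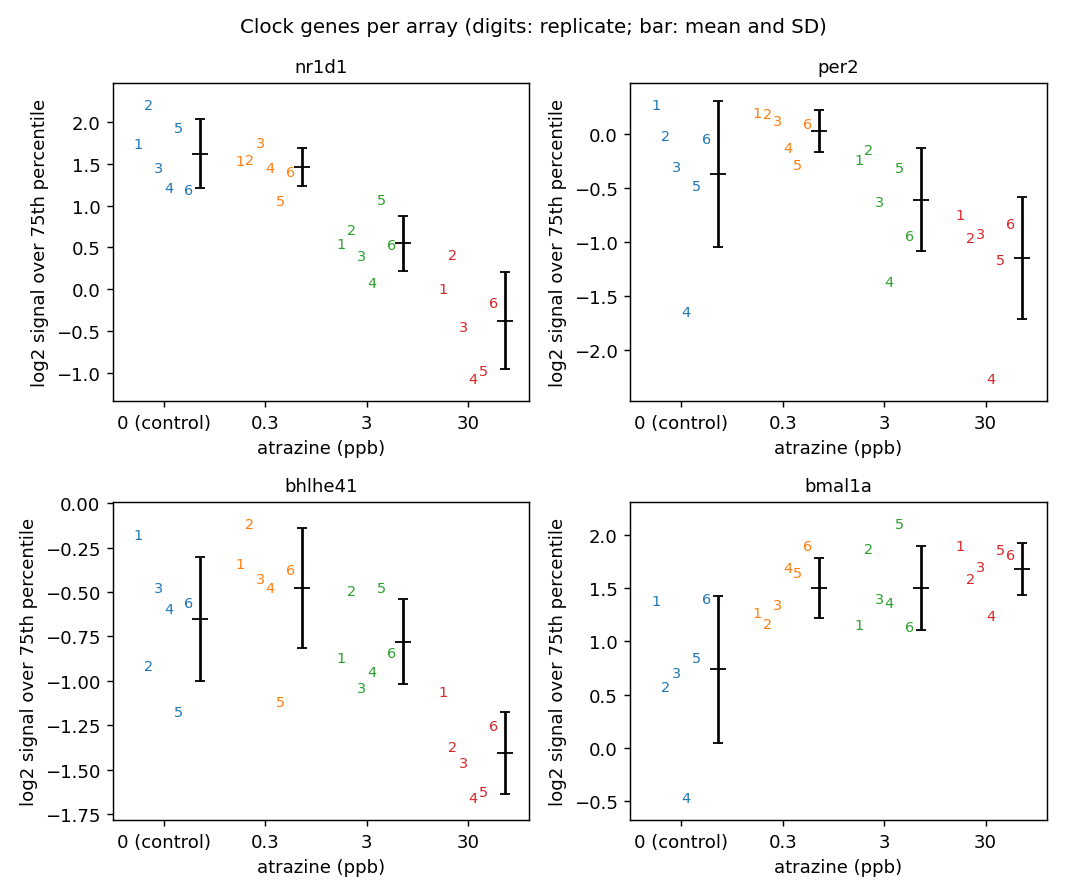
Log2 signal over each array's 75th percentile for the clock genes nr1d1, per2, bhlhe41 and bmal1a by atrazine dose; digits are replicate numbers and bars are means with SD (n = 6 arrays per dose). The mean of nr1d1 is lower at 3 ppb and lowest at 30 ppb; per2 was chosen after its values were seen.

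With the 3 doses pooled against control, most ribosomal protein genes fell, as did some genes of leukocytes and other tissues, and a few neuronal genes rose. Among genes that rose were cbln2a (log2 change 2.43 ± 0.46, SE, n = 18 exposed and 6 control arrays, adjusted p = 0.0349), the synaptic kinase camk2a (1.54 ± 0.40, adjusted p = 0.0447), the GABA receptor subunit gabbr2 (1.27 ± 0.28, adjusted p = 0.0387), the glutamate receptor subunit gria2a (0.91 ± 0.23) and the neuronal transcription factor neurod6a (1.58 ± 0.38). Among genes that fell were the chemokine ccl39.1 (-2.58 ± 0.38, adjusted p = 0.0223), adam8a (-3.12 ± 0.47, adjusted p = 0.0223), the neutrophil gene mpx (-3.03 ± 0.59, adjusted p = 0.0361) and the ribosomal protein gene rplp1 (-1.09 ± 0.22, adjusted p = 0.0376). Lower also were the dioxin-responsive enzyme gene cyp1a (-2.88 ± 0.74, adjusted p = 0.044), the yolk protein gene vtg5 (-2.06 ± 0.54), the muscle gene smyd1a (-3.89 ± 0.97), the stress gene sesn1 (-1.21 ± 0.22) and hsd11b2, which inactivates cortisol (-2.32 ± 0.53). Of the clock genes, nr1d1 (-1.08) and per1a (-0.65) fell and bmal1a (0.83) rose.

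For all exposed arrays 2674 targets passed, 1428 higher and 1246 lower, 287 and 526 of them with a gene symbol, and 17640 had an unadjusted p under 0.05. Of the members of the fixed lists, 54 of 80 ribosomal protein, 14 of 32 leukocyte, 8 of 34 interferon-response, 7 of 60 muscle and 3 of 42 liver genes fell, and 3 of 30 synaptic, 1 of 15 GABA, 4 of 23 glutamate, 2 of 37 neuropeptide and 3 of 47 neuronal differentiation genes rose. At the preset correlation camera called 24 of the 40 lists (7 up, 17 down) and fry called 20. With an estimated correlation 0 were called (smallest adjusted p = 0.195 with an estimated correlation). The count was 4022 with slide and 3639 with scan day as a block; limma called 0 within scan day 1 (6563 at unadjusted p under 0.05) and 0 within scan day 2 (11330). Single arrays decided it: 0 passed without control replicate 4 or control replicate 5, and 10211 passed without control replicate 1. Without the 3 arrays with weak signal 1 target passed.

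Doses were compared with each other to test whether the responses differ. The 4 chemokine genes ccl34b.4 (-5.33 ± 0.62), ccl38a.4 (-5.82 ± 0.69), ccl38a.5 (-4.17 ± 0.60) and ccl38.1 (-3.48 ± 0.56) were lower at 3 ppb than at 0.3 ppb (log2, SE, n = 6 per group but 5 at 0.3 ppb for ccl34b.4, adjusted p from 7.43e-04 to 0.0338), as was aanat2 (-2.49 ± 0.32, adjusted p = 0.00158). From 3 to 30 ppb, ccl34b.4 (5.07 ± 0.59, adjusted p = 0.00152), ccl38a.4 (4.94 ± 0.69, adjusted p = 0.0112) and aanat2 (2.00 ± 0.32, adjusted p = 0.05, just under the threshold) were higher. nr1d1 was lower at 30 than at 0.3 ppb (-1.84 ± 0.25, adjusted p = 0.0144). These were all the named genes among 7, 3 and 2 targets that passed for 3 against 0.3, 30 against 3 and 30 against 0.3 ppb, with 2742, 1877 and 1588 at an unadjusted p under 0.05; the other targets have no gene name. Any difference among the 4 groups passed for 10 targets, 6 of them named genes: these 4 chemokine genes, aanat2 and nr1d1. In the order 3 against 0.3, 30 against 0.3, 30 against 3 and any difference, the counts were 6, 3, 2 and 9 with slide and 7, 2, 3 and 10 with scan day as a block. Within scan day 1 limma called 0, 0, 1 and 0, with 1669, 805, 1771 and 2217 at an unadjusted p under 0.05, and within scan day 2 it called 0, 0, 0 and 0, with 1001, 2631, 2547 and 4868. Without control replicate 1 the counts were 14, 2, 6 and 480, and the count for 30 against 0.3 ppb was 0 without 0.3 ppb replicate 1, 2 or 4 or 30 ppb replicate 3, 4 or 5.

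Gene lists also differed between doses, and 4 of these differences held with an estimated correlation. Genes of photoreceptors and the pineal gland, such as the visual retinoid carrier gene rbp3, had a median log2 difference of -1.80 at 3 against 0.3 ppb, with 24 of 55 lower adjusted over the list alone and adjusted p = 0.0129 with an estimated correlation. Interferon-response genes had a median of -0.70 at 3 against 0.3 ppb, with 10 of 34 lower adjusted over the list alone (adjusted p = 0.0346 with an estimated correlation), and of 0.61 at 30 against 3 ppb, with 11 higher adjusted over the list alone (adjusted p = 0.0366 with an estimated correlation). In the same comparisons the leukocyte list had medians of -0.68 and 0.59, with 0 of 32 past the threshold adjusted over the list alone (adjusted p = 0.139 and 0.171 with an estimated correlation). Circadian clock genes had a median of -0.37 at 30 against 0.3 ppb, with 13 lower and 1 higher of 37 adjusted over the list alone (adjusted p = 0.0346 with an estimated correlation). At the preset correlation camera called 20, 14 and 9 lists for 3 against 0.3, 30 against 0.3 and 30 against 3 ppb, and fry called 0 for each.

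Neuronal lists were higher than in controls at each dose, in the order 0.3, 3 and 30 ppb. Medians of log2 change were 0.84, 0.88 and 0.70 for the 30 synaptic genes, 1.2, 1.00 and 0.97 for the 15 GABA genes, 0.95, 0.89 and 0.83 for the 23 glutamate genes, 0.98, 1.11 and 1.13 for the 37 hypothalamic neuropeptide genes and 0.83, 0.95 and 0.73 for the 47 neuronal differentiation genes. Adjusted p from camera ranged from 6.43e-13 to 0.00434, and adjusted p = 0.263 to 0.491 with an estimated correlation, so that none held. Adjusted over the list alone, 24, 11 and 4 synaptic genes, 11, 1 and 1 GABA genes, 14, 11 and 8 glutamate genes, and 0, 12 and 17 neuronal differentiation genes rose. Radial glia genes such as mlc1 had medians of 0.40, 0.64 and 0.52 (camera adjusted p = 0.0204, 0.0204 and 0.002; adjusted p = 0.574, 0.574 and 0.44 with an estimated correlation), and 1, 0 and 2 rose adjusted over the list alone. The serotonin (0.17, 0.43, 0.30), catecholamine (0.43, 0.49, 0.48), cholinergic (0.38, 0.59, 0.36) and oligodendrocyte (0.14, 0.40, 0.09) lists were not called, with adjusted p from 0.0951 to 0.75. Liver transcripts were high on control replicate 4, where the synaptic list was lowest among controls at -2.50 (next -0.71). The glutamate (-2.53, next -0.73) and neuropeptide (-3.60, next -0.85) lists were lowest there too, so this array carries part of these rises.

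Immune, blood and vessel lists were lower at each dose. In the same order of doses, medians were -0.97, -1.67 and -0.85 for the 32 leukocyte genes, -0.42, -1.02 and -0.47 for the 34 interferon-response genes, -0.64, -0.82 and -0.61 for the 33 inflammation genes, -0.82, -0.97 and -0.87 for the 30 erythrocyte genes, -1.07, -1.10 and -1.19 for the 10 haemoglobins and -0.50, -0.30 and -0.47 for the 33 endothelial genes. Adjusted p from camera ranged from 1.54e-25 to 0.00198, and adjusted p = 0.237 to 0.456 with an estimated correlation. Over all targets, 3 leukocyte, 6 interferon-response and 1 inflammation gene fell at 3 ppb and 0 at the other doses. Adjusted over the list alone, 12, 23 and 12 leukocyte genes, 0, 16 and 0 interferon-response genes, 0, 9 and 0 inflammation genes, 6, 6 and 10 erythrocyte genes, 3, 0 and 0 haemoglobins and 10, 3 and 8 endothelial genes fell.

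Markers of other tissues were mostly lower at each dose as well. Medians were -2.44, -1.84 and -1.85 for the 42 liver genes, -1.89, -2.77 and -3.43 for the 60 skeletal muscle genes, -0.92, -1.44 and -0.41 for the 39 epidermis and gill genes and -0.92, -0.40 and -0.74 for the 42 genes of meninges, bone and fibroblasts. Adjusted p from camera ranged from 2.02e-28 to 0.0158, and adjusted p = 0.256 to 0.725 with an estimated correlation. Adjusted over the list alone, 30, 0 and 0 liver genes and 0, 0 and 41 muscle genes fell, and 0 genes of the other 2 lists at each dose. Control replicate 4 carries part of the liver difference, with a list level of 6.22 against 1.91 on the next control. Photoreceptor and pineal genes had medians of 1.42, -0.29 and 0.56 (camera adjusted p = 8.09e-12, 0.00457 and 0.0138; adjusted p = 0.263, 0.604 and 0.672 with an estimated correlation), with 24 higher at 0.3 ppb adjusted over the list alone. Germ cell genes had a median of -0.65 at 0.3 ppb (adjusted p = 1.64e-04; adjusted p = 0.456 with an estimated correlation) and were not called at 3 and 30 ppb (adjusted p = 0.209 and 0.198). Genes of motile cilia had medians of 0.02, -0.02 and 0.65 and were called at 30 ppb (adjusted p = 1.49e-05; adjusted p = 0.395 with an estimated correlation). Pituitary genes had medians of 1.08, 0.52 and 0.66 and were called at 0.3 ppb (adjusted p = 0.0236; adjusted p = 0.604 with an estimated correlation).

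**Figure D3:**
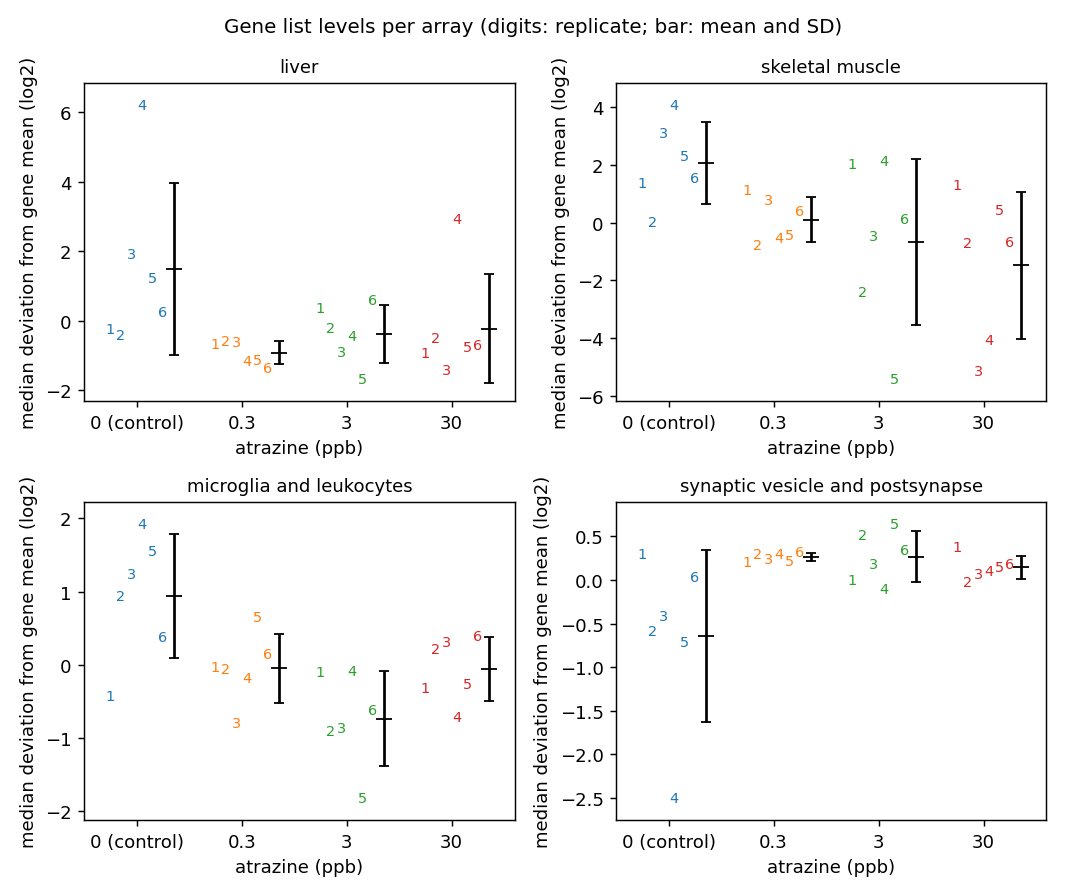
Level of the liver, skeletal muscle, leukocyte and synapse lists on each array by atrazine dose, as the median deviation (log2) of a list's genes from their mean over all arrays; digits are replicate numbers and bars are means with SD (n = 6 arrays per dose). Control replicate 4 has the highest liver level, 6.22, and the lowest synapse level, -2.50.

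Ribosomal protein genes were lower at each dose, with medians of -0.70, -0.80 and -0.82, and 75, 76 and 77 of 80 fell adjusted over the list alone. Cell cycle genes had medians of -0.73, -0.38 and -0.44, with 20, 1 and 0 of 49 lower adjusted over the list alone, and nuclear oxidative phosphorylation genes -0.37, -0.24 and -0.42, with 0 of 90 at each dose. Xenobiotic metabolism genes had medians of -0.70, -0.62 and -0.62, with 0, 1 and 1 of 46, and oxidative stress genes -0.28, -0.32 and -0.36, with 0, 0 and 4 of 33. Adjusted p from camera for these 5 lists ranged from 6.60e-45 to 0.00198, and adjusted p = 0.256 to 0.555 with an estimated correlation. The liver, muscle and leukocyte lists were lower at the same doses. Cholesterol synthesis genes had medians of -0.04, 0.41 and 0.34 and were called at 3 and 30 ppb (adjusted p = 0.00708 and 0.00484; adjusted p = 0.367 and 0.349 with an estimated correlation), with 0 past the threshold adjusted over the list alone.

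The steroid synthesis list was called down at each dose (adjusted p = 0.0126, 0.00685 and 0.0283; adjusted p = 0.256 at each with an estimated correlation), with 6, 5 and 7 of 27 lower adjusted over the list alone. Its medians were -0.34, 0.03 and -0.15 and its means -0.62, -0.48 and -0.50, so that median and test differed in sign at 3 ppb. The proteasome list was called down at 3 ppb (adjusted p = 0.036; adjusted p = 0.681 with an estimated correlation), with a median of 0.06 and a mean of -0.22; 4 of its 48 genes fell, among them psmb8a, psmb9a and psmb13a. At 0.3 and 30 ppb its median was -0.05 and it was not called (adjusted p = 0.345 and 0.113). The clock list was called up at 0.3 ppb (median 0.18, adjusted p = 0.00801; adjusted p = 0.395 with an estimated correlation) and down at 30 ppb (median -0.09, adjusted p = 0.036; adjusted p = 0.5 with an estimated correlation), where 6 genes rose and 8 fell adjusted over the list alone; at 3 ppb its median was 0.09 and the test pointed down (adjusted p = 0.209). Not called at any dose were the lists of the reproductive axis (0.54, 0.41, 0.44), sex steroid receptors and aromatase (0.18, 0.37, 0.26), the stress axis (0.22, 0.26, 0.20), the thyroid axis (0.21, 0.37, 0.16), immediate early genes (-0.09, 0.11, -0.13), heat shock and unfolded protein response (0.05, -0.01, 0.04) and methylation of DNA and histones (0.21, 0.24, 0.06). Among these the test pointed down beside a positive median for the stress axis, thyroid and immediate early lists at 3 ppb and for the heat shock list at 30 ppb.

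Of the 40 lists, camera called 26 at 0.3 ppb (9 up, 17 down), 25 at 3 ppb (7 up, 18 down) and 26 at 30 ppb (9 up, 17 down), and 22 at all 3 doses. With an estimated correlation it called 0, 0 and 0, with smallest adjusted p of 0.256, 0.237 and 0.256, and fry called 12, 10 and 7. With slide as a block the counts were 26, 24 and 26, and with scan day 26, 25 and 26; within scan day 1 they were 24, 28 and 24, and within scan day 2 they were 26, 25 and 23.

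**Figure D4:**
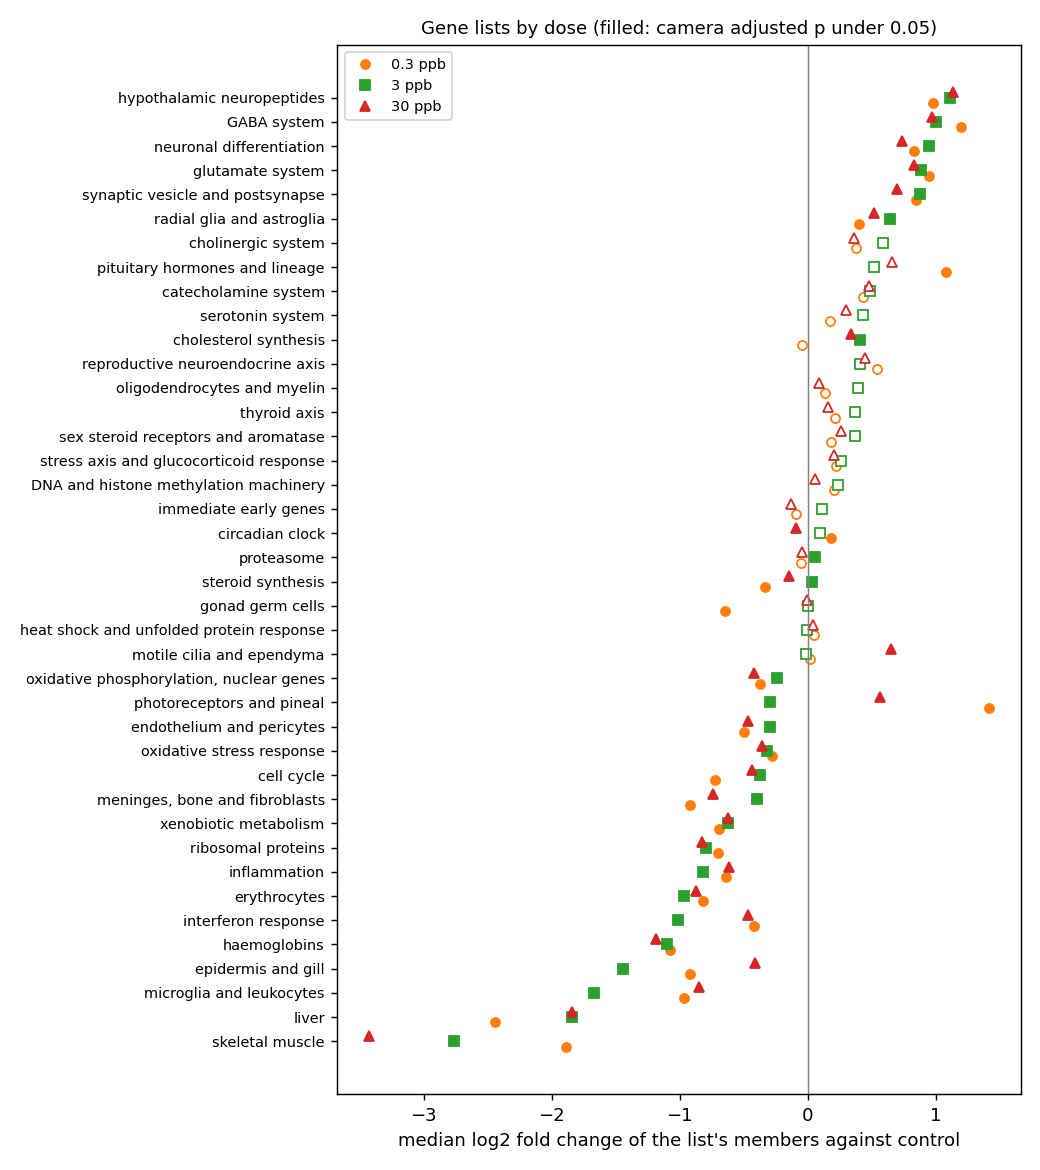
Median log2 fold change against control of each of 40 gene lists at 0.3, 3 and 30 ppb, sorted by the value at 3 ppb; filled symbols have a camera adjusted p under 0.05 at the preset correlation of 0.01. The muscle list lies lowest, at -2.77 for 3 ppb, and the hypothalamic neuropeptide list highest, at 1.11.

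None of the 20 neuroendocrine genes fixed in advance passed at any dose. Log2 changes against control, at 0.3, 3 and 30 ppb, were 1.40, 2.02 and 1.64 for gnrh2 and 1.34, 1.3 and 2.12 for gnrh3, which encode gonadotropin-releasing hormones, 2.12, 1.51 and 1.39 for the kisspeptin gene kiss2, and 1.22, 1.05 and 1.34 for brain aromatase, cyp19a1b. They were -0.83, -0.70 and -0.81 for the androgen receptor gene ar, 0.40, 0.45 and 0.53 for the estrogen receptor gene esr1, -0.57, -0.10 and -0.54 for esr2a and -0.72, -0.37 and -0.58 for esr2b. For the serotonin synthesis genes they were 0.46, 0.38 and 0.37 (tph2) and 1.36, 0.37 and 1.2 (tph1a), for the serotonin transporter gene slc6a4a -0.23, -0.07 and -0.24, and for the dopamine synthesis gene th 0.29, 0.46 and 0.09. The stress axis genes crhb (1.24, 1.18, 1.36) and nr3c1 (0.22, 0.13, 0.17) had SEs of 0.54 and 0.17. Log2 changes were 4.12, 1.95 and 1.97 for the stress hormone precursor gene pomca, 3.58, 0.60 and 1.33 for lhb, 3.56, 1.78 and 1.91 for cga and 1.52, 0.41 and 0.66 for fshb, which encode gonadotropin subunits, with SEs of 1.93, 2.2, 2.35 and 1.61. In controls pomca was well above background on 4 of 6 arrays, lhb and gnrh3 on 3 and cga and fshb on 2. The neuropeptide genes oxt (3.48, 1.99, 3.00) and avp (2.18, 1.02, 1.94) had SEs of 1.68 and 0.97. The smallest adjusted p among these genes at any dose was 0.151, for gnrh2 at 3 ppb.

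The changes at the 3 doses were alike across genes. Across the 72590 targets, which are not independent replicates, log2 changes correlated at 0.760 between 0.3 and 3 ppb, 0.784 between 0.3 and 30 ppb and 0.802 between 3 and 30 ppb, and 75.8%, 79.7% and 80.2% had the same sign. All 3 comparisons used the same 6 controls. With 3 controls for each dose the mean correlations over 20 ways of dividing them were 0.348, 0.369 and 0.362. In 100 simulated sets without a dose effect the mean correlations were 0.548, 0.563 and 0.580, and 17, 17 and 10 sets had one as large; 2, 3 and 5 sets had a covariance as large as the measured 0.425, 0.443 and 0.428. At 3 and 30 ppb 2 targets passed at both, both lower and without a gene name.

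The authors' lists hold 12179 entries at 0.3 ppb (12059 distinct probes), 13645 at 3 ppb and 12449 at 30 ppb (12326 distinct probes). Their highest listed p was 0.05, and 99.9%, 99.8% and 99.8% of entries had the same sign here. The lists were chosen on these same arrays, so the shared signs are no independent support. Of the targets behind these probes, 0, 109 and 3 passed after adjustment over all targets. Matching the lists by probe gave 11285 entries between 0.3 and 3 ppb, 10968 between 0.3 and 30 ppb and 11378 between 3 and 30 ppb. Of these, 11091, 10858 and 11220 had 1 direction. All 3 doses share the same 6 controls, which by itself makes such lists alike. Of the 2254 genes they list as altered at all doses, 1027 were found by symbol; 1005 had the listed direction at all 3 doses, and 323 passed here for all exposed arrays.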

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

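The tests of explanations given here were chosen after the results were seen. Of 533 groups of 6 arrays tested, 40 held 1 array far from the other 5 by Dixon's test; chance puts about 1 in 20 groups past it. Control replicate 4 accounts for 9 of the 40, 0.3 ppb replicate 3 for 8, and control replicate 1, 3 ppb replicate 5 and 30 ppb replicate 4 for 4 each.

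Control replicate 4 lay far above the other controls for the liver list (6.22 log2, next 1.91) and far below them for the serotonin (-1.73), glutamate (-2.53), neuropeptide (-3.60) and synapse (-2.50) lists. It was also far off for sesn1 (4.11), tph1a (-6.17), crhb (-1.98) and neurod6a (-3.02).

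The pattern this array belongs to is the large set of genes that differ between all exposed arrays and the controls. Weak probes near background are argued against as the whole cause, since 5541 of 23126 targets passed with probes well above background on all arrays, 1239 of them among the 2674. Weak arrays stay open: 1 target passed without the 3 arrays and 2 with array weights, but 101 of 216 sets of arrays with the same make-up left as few when left out. RNA of non-neural tissue in the control samples may contribute. In 5 of the 6 controls the non-neural lists were above and the neuron lists below the exposed mean. Control replicate 1 is the exception, and control replicate 2 differed with a liver level of -0.41. These lists were picked after the results were seen, so this is no separate test. Some exposed arrays, such as 3 ppb replicates 1 and 4, lay that way round too. Slide position cannot be told apart from dose in this or any other comparison of the doses, as 0 groups lay at more than 1 position. The exposure itself stays open, untested.

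Control replicate 1 lay far below the other controls for ccl34b.4 (0.76), gig2i (-3.23) and psmb8a (-2.49) and above them for hs3st1l2 (-0.91).

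At 3 ppb the chemokine genes differed from 0.3 ppb by a test of the difference: ccl34b.4 (-5.33, adjusted p = 7.43e-04), ccl38a.4 (-5.82, 7.43e-04), ccl38a.5 (-4.17, 0.00776) and ccl38.1 (-3.48, 0.0338). At 30 ppb ccl34b.4 (5.07, 0.00152) and ccl38a.4 (4.94, 0.0112) were higher than at 3 ppb. No control enters the comparison of 3 with 0.3 ppb, so raised controls cannot produce the differences found there. These genes were picked because they passed in that comparison, so their median of -4.75 there is no separate test of raised controls. A lower share of leukocytes stays open for them. The leukocyte list had a median of -0.68 at 3 against 0.3 ppb, but genes picked for large falls lie beyond a list median whatever the cause. For ccl39.1, which also fell against control, raised controls stay open, as it differed by -0.47 in that comparison. For the interferon-response list camera argues against raised controls as the whole cause (adjusted p = 0.0346 with an estimated correlation at 3 against 0.3 ppb). A part stays open, as the list level was 0.51 in controls, 0.07 at 0.3 ppb and 0.02 at 30 ppb. The tests differ, as fry called 0 lists at 3 against 0.3 ppb. Fewer leukocytes cannot be told apart from a change within cells for this list, since its median of -0.70 is near that of the leukocyte list. A shared origin of the 3 ppb fish, such as a tank, a clutch or an immune-gene haplotype, could give the same pattern and cannot be told apart from dose: 6 of 6 arrays of 3 ppb were below all other arrays for ccl34b.4 and ccl38a.4, and the labels give no origin.

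The clock gene nr1d1 was lower at 30 ppb than in controls (-2.00, adjusted p = 0.00355) and than at 0.3 ppb (-1.84, adjusted p = 0.0144). Raised controls are argued against as the whole cause of the first difference, since no control enters the second (adjusted p = 0.0144). A difference in the time of day of sampling could give the same pattern and cannot be told apart from dose, as the labels give no sampling time. Slide position and a shared tank or clutch cannot be told apart from dose either. Repressor-arm genes of the clock differed from activator-arm genes by -0.82 log2 at 30 against 0.3 ppb, but the list of arms was written after the values were seen, so this supports no explanation. An effect of dose stays open.

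Pineal aanat2 was lower at 3 than at 0.3 ppb (-2.49, adjusted p = 0.00158) and higher at 30 than at 3 ppb (2.00, adjusted p = 0.05).

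At 0.3 ppb, replicate 3 lay far below the other 5 arrays for the pituitary list (-2.07), fshb (-7.18), lhb (-3.37), cga (-7.05), pomca (0.64), cldng (-6.45), gcgb (-3.57) and esr2b (-3.55). Replicate 2 was far below for dennd4a (-1.15) and ccl39.1 (-3.92). Replicate 1 was far below for avp (0.78) and oxt (0.27), and replicate 5 for bhlhe41 (-1.12).

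At 3 ppb, replicate 5 lay far above the others for the radial glia (0.60) and proteasome (0.47) lists and far below for gig2g (-6.50) and per1a (-1.63). Replicate 4 lay far below for tph1a (-5.20) and esr1 (-3.43).

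At 30 ppb, replicate 4 had the lowest share of spots well above background (41.6%, next 75.6%), the highest liver level (2.92) and low arr3a (-3.45) and per2 (-2.26). Replicate 6 lay far below the others for dennd4a (-2.16) and gria2a (-0.45), and replicate 3 for avp (0.67) and oxt (-1.73).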

How the results depend on the processing

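The alternatives that left out arrays with weak signal or raised liver transcripts, kept to genes paired with RefSeq, or used 1 scan day were chosen after the data were seen, as were the list tests with median scaling, scan day as a block, single arrays left out, or a replicate block with an estimated correlation. The causes of the changes given here were not tested, except that fewer arrays or targets entered where arrays or probes were left out. Called directions held and counts moved. Alternatives to the main fit (48 settings with the main one) gave 32251 values of 744 single-gene results. Of these, 29251 kept direction and side of the threshold, 1657 no longer passed and 634 newly passed. A further 709 turned to the other direction where the main result had not passed, and 0 turned around a called direction. Signal over background limits what the weak arrays can show: 35.8%, 37.3% and 41.6% of their spots were well above it. The normexp correction was run on the median spot signal, since the mean signal named in the plan was absent from the files; the planned version on the mean signal was not run.

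At 3 ppb against control, where 111 targets passed, the count was 487 with quantile normalization, 498 with median scaling, 14 with normexp, 62 with the authors' values, 35 with no probe filter, 707 with probes well above background on all 24 arrays, 389 for each probe by itself, 392 with a trended robust prior, 61 with array weights and 1 with only 2 groups in the fit. It was 17 with slide as a block, 175 over RefSeq genes, and 0 within scan day 1 and within scan day 2. It was 3 without the 3 weak arrays, 2 without control replicate 4 as well and 0 without control replicate 5 as well. The unmoderated per-gene test had 8871 at unadjusted p under 0.05, 7042 of them with a change of at least 1.5-fold, and 0 after adjustment. Leaving out single arrays gave 4 to 4108. In the order of replicates 1 to 6, controls gave 4108, 29, 44, 18 and 5 (replicate 6 stayed within 1.5 times), and 0.3 ppb gave 35 (replicate 1), 36 (2), 44 (4) and 36 (6). Arrays of 3 ppb gave 388, 4, 6, 421, 5 and 29, and arrays of 30 ppb gave 41, 46, 56, 281, 43 and 54.

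At 0.3 ppb, where 0 passed, the count was 1 with quantile normalization, with median scaling and with the trended robust prior. The unmoderated test had 10262 at unadjusted p under 0.05, 7884 with at least 1.5-fold, and 1 after adjustment. Leaving out single arrays gave 0 to 814, with 814 without control replicate 1, 3 without 0.3 ppb replicate 2, 1 without 3 ppb replicate 1, 2 or 3 or 30 ppb replicate 2, and 0 without any other array. At 30 ppb, where 3 passed, the count was 5 with median scaling, 1 with the authors' values, 45 with probes above background on all arrays, 10 for each probe by itself, 11 with the trended robust prior, 0 with only 2 groups in the fit, 9 over RefSeq genes, and 0 within each scan day. It was 1 without the weak arrays and control replicate 4, and 0 without control replicate 5 as well. The unmoderated test had 7230, 5778 with at least 1.5-fold, and 0 after adjustment. Leaving out single arrays gave 3 to 1052: 1052 without control replicate 1, 6 without control replicate 2, and 5 without 3 ppb replicate 1 or 5.

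For all exposed arrays against control, where 2674 passed, the count was 4022 with slide as a block, 5117 with quantile normalization, 739 with median scaling, 393 with normexp, 5 with no probe filter, 5541 with probes above background on all arrays, 5557 for each probe by itself, 5314 with the trended robust prior and 2 with array weights. It was 0 within each scan day, 1 without the weak arrays, 1 without control replicate 4 as well and 0 without control replicate 5 as well. Leaving out single arrays gave 0 to 10211. In the order of replicates 1 to 6, controls gave 10211, 1007, 30, 0, 0 and 7019, 0.3 ppb gave 950, 39, 6, 4, 721 and 4, 3 ppb gave 4016, 4, 6, 4304, 303 and 659, and 30 ppb gave 45, 477, 93, 1774, 181 and 1216.

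For the trend, where 3 passed, the count was 20 with probes above background on all arrays, 10 for each probe by itself, 7 with the trended robust prior, 5 with array weights, 5 over RefSeq genes and 0 within each scan day. Single arrays gave 3 to 329 (329 without control replicate 1, 5 without 3 ppb replicate 1). For 3 against 0.3 ppb, where 7 passed, it was 3 with normexp, 0 with probes above background on all arrays, 11 for each probe by itself, 99 with array weights and 0 within each scan day. Single arrays gave 5 to 14, the latter without control replicate 1. For 30 against 0.3 ppb, where 2 passed, it was 1 with normexp, 1 with the authors' values, 4 with probes above background on all arrays, 13 with array weights, 1 over RefSeq genes, and 0 within each scan day and without the weak arrays, with or without control replicates 4 and 5. Single arrays gave 0 to 2, with 0 without 0.3 ppb replicate 1, 2 or 4 or 30 ppb replicate 3, 4 or 5. For 30 against 3 ppb, where 3 passed, it was 1 with normexp, 0 with probes above background on all arrays, 7 for each probe by itself, 69 with array weights, 1 within scan day 1 and 0 within scan day 2. Single arrays gave 1 to 6 (6 without control replicate 1, and 1 without 3 ppb replicate 2 or 3 or 30 ppb replicate 6).

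For any difference among the 4 groups, where 10 passed, the count was 27 with quantile normalization, 25 with median scaling, 4 with normexp, 5 with the authors' values, 47 with probes above background on all arrays, 17 for each probe by itself, 27 with the trended robust prior, 4 and 3 without the weak arrays and control replicate 4, then 5, and 0 within each scan day. Single arrays gave 7 to 480 (480 without control replicate 1, 16 without 3 ppb replicate 4). The targets that passed at both 3 and 30 ppb numbered 2, and 4 with quantile normalization. Correlations of log2 changes between doses were 0.348, 0.369 and 0.362 with the controls divided between the doses.

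The number of lists called was 0 at each dose with an estimated correlation, also with a replicate block, without the weak arrays, and without control replicates 4 and 5 as well. It was 12, 10 and 7 with fry. Leaving out single arrays gave 23 to 27 at 0.3 ppb, 24 to 26 at 3 ppb and 23 to 27 at 30 ppb.

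Arrays that share a replicate number share a slide, so the replicate block is the slide block: it gave 17 at 3 ppb, 4022 for all exposed arrays and 1 target shared by 3 and 30 ppb. With group means removed, 20 of 36 pairs of same-numbered arrays correlated at over 0.1. Their mean correlation was 0.096, against -0.018 for differently numbered arrays of other groups. Of the 24 arrays, 13 correlated best with an array of their own number. Arrays of 1 slide were thus somewhat alike, which the main fit left out of account. The labels do not call the number a pairing of fish, and it was not taken as one.

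The chemokine gene ccl34b.4 passed at 3 ppb in 42 of 46 alternatives, with adjusted p from 6.76e-07 to 0.767, and nr1d1 passed at 30 ppb in 42 of 47 (4.19e-05 to 0.748) and for the trend in 40 of 42 (1.13e-04 to 0.860). At 3 against 0.3 ppb, ccl34b.4 and ccl38a.4 each passed in 39 of 41 and ccl38.1 in 18 of 41. At 30 against 0.3 ppb nr1d1 passed in 31 of 42. Other genes that fell or rose at 3 ppb passed in fewer alternatives and kept their direction: ccl38a.4 in 40 of 46, psmb9a in 36 of 47, c1qa in 32 of 47, aanat2 in 27 of 46, rac2 and coro1a each in 15 of 47, psmb8a and osgepl1 each in 14 of 46 and wdr48b in 11 of 47.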

Other observations

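The tests in this part were chosen after the results were seen. Pituitary hormone genes varied widely among the arrays of a group. The opioid and stress hormone precursor gene pomca ranged from -5.0 to 7.26 log2 over controls, and from 0.64 to 6.51 at 0.3 ppb, -1.05 to 6.74 at 3 ppb and -0.51 to 6.22 at 30 ppb. The gonadotropin gene lhb ranged from -5.79 to 4.47 in controls and the gonadotropin gene fshb from -7.39 to 0.60. The hypothalamic peptide gene oxt ranged from -3.0 to 5.71 in controls and from -1.73 to 6.33 at 30 ppb.

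Pineal and photoreceptor genes moved by group as well. The photoreceptor gene rbp3 lay between -0.20 and 1.06 on the 6 arrays of 0.3 ppb and between -4.03 and -2.45 on the 6 of 3 ppb, while controls ranged from -5.96 to 0.67. The transcription factor gene crx, chosen after its values were seen, lay between -0.78 and 0.16 at 0.3 ppb and between -6.52 and -3.24 at 3 ppb. A further 2 genes chosen after their values were seen, ifng1 and irf1b, an interferon gene and an interferon-response regulator, had log2 changes of -2.60 ± 0.73 and -1.43 ± 0.35 (SE, n = 6 per group) at 3 ppb against control, with adjusted p of 0.101 and 0.0775. The clock gene per2, chosen likewise, had a log2 difference of -1.18 at 30 against 0.3 ppb.

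To ask whether other groupings of the arrays give as many calls, 100 splits into groups of the same sizes were counted for each comparison, the real one included. These splits regroup the arrays across slides, although each slide held 1 array per dose, so they do not exclude chance by themselves. Exchanges with slides kept are given in the next paragraph. At 3 ppb against control, where 111 passed, 2 splits gave as many and the highest other gave 216, but with slides kept chance stayed open. At 30 ppb chance was unlikely but, with slides kept, not excluded (3 passed, 2 splits, highest other 61). At 0.3 ppb 0 passed, so that all 100 splits gave as many whatever their counts (highest other 7), and chance was not tested. For all exposed arrays (2674 passed) 1 split gave as many and the highest other gave 820, so that chance was unlikely but, with slides kept, not excluded. The same holds for the trend (3 passed, 3 splits, highest other 4526), for 3 against 0.3 ppb (7 passed, 2 splits, highest other 1645) and for 30 against 0.3 ppb (2 passed, 2 splits, highest other 2). For any difference (10 passed, 3 splits, highest other 81) and for 30 against 3 ppb (3 passed, 1 split, highest other 2) chance stayed open with slides kept. Single other splits gave 4526, 1645, 81 and 61 calls, several times the real counts, and the reason was not tested. For lists at 0.3, 3 and 30 ppb, where 26, 25 and 26 were called, 14, 17 and 11 splits gave as many, with 29, 28 and 33 as the highest other. The median over the other splits was 20, 21 and 20 lists of 40. Chance stayed open, and list calls at the preset correlation are weak evidence in these data.

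To keep slides, labels were exchanged within slides alone, for 32 splits per pair of groups and 100 for the other comparisons, the real one included. At 3 ppb against control 3 of 32 splits gave as many calls, with 4326 as the highest other, so that chance stayed open when slides were kept, and with slide as a block 17 passed. Chance also stayed open for 30 against 3 ppb (2 of 32, highest other 65) and for any difference (5 of 100, highest other 3001). It was unlikely, though not excluded, at 30 ppb against control (1 of 32, highest other 1), for 3 against 0.3 ppb (1 of 32, highest other 0) and for 30 against 0.3 ppb (1 of 32, highest other 1). The share 1 of 32 is the smallest that these exchanges can give. Chance was likewise unlikely, though not excluded, for all exposed arrays (2 of 100, highest other 9719) and the trend (4 of 100, highest other 4434). There, other exchanges gave more calls than the real labels. The gene lists were not split within slides.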
